A study of Homo sapiens with 12 samples.

How the data were processed

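Gene expression was measured in HCC827, a human non-small cell lung cancer line that carries an activating EGFR mutation, on 12 Illumina bead arrays. The cells had been grown alone or in co-culture with MRC-5, a line of normal human lung fibroblasts, and had or had not received gefitinib, an inhibitor of the EGFR kinase. The 4 groups of 3 arrays were DMSO monoculture, gefitinib monoculture, co-culture and co-culture with gefitinib, and each array was placed in its group by its title. Per the labels' protocols, gefitinib was given at 0.5 µM after 24 h, the cells were rinsed with PBS, and the RNA was taken 48 h later. The co-culture used inserts with 1 µm pores, so that the fibroblasts shared the medium with the HCC827 cells. The labels name one medium for routine growth and another for the co-culture. Which medium the monoculture arms received during the last 48 h, and whether gefitinib was present then, is not given in the sources used here.

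The values from the authors were of 2 kinds. The scanner table holds a linear intensity per probe with no background subtraction, per the file headers and its values, and beside each intensity a detection p-value of the probe, per the file headers. How that p-value was computed is not given in the sources used here. A second deposited table holds intensity values that the authors had normalized between arrays by a method not given in the sources used here. These values were linear, uncentred and monotone in the scanner intensities, with column medians between 103.586 and 104.67. The image software is not given in the sources used here either. Biotin-labelled cRNA had been made with an Ambion MessageAmp kit, per the labels' protocols.

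In the scanner table, the rows of the 6 monoculture arrays followed the probe names, with correlations of at least 0.99988 with the authors' normalized values of the same array. The rows of the 6 co-culture arrays stood in another order, with correlations of at most 0.00105. Each of their rows was therefore given the probe name whose 6 values in the authors' normalized table it matched. All rows (100%) of the 48106 matched were mutual best matches, with a median distance of 0.00207 on the log2 scale against 0.07203 for the next best row. The same procedure was tested on the monoculture arrays after their rows had been shuffled, and 100% of 48104 rows returned to their own probe. When each co-culture array was left out of the matching, its correlation with its own normalized values was at least 0.99986. The scanner table held 48107 probes, of which 3 had a missing value and were left out. The probe names of the co-culture values thus rest on the authors' normalized table.

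Gene names came from the platform annotation paired with the probes. Of the 48104 probes used, 30113 had 1 gene symbol, 8 had several and 17983 were unnamed here. Looking the symbols up through their gene identifiers changed 0 of them. Background was corrected with limma's neqc (normexp with the background taken from the detection p, offset 16), followed by quantile normalization and log2. A probe was kept when its detection p was under 0.05 on at least 3 of the 12 arrays, which left 18238 probes with 1 symbol. Each gene was represented by its kept probe with the highest mean, which gave 13577 genes, 3602 of them with more than 1 kept probe. Levels are normalized log2 intensities and are compared only within a probe. A gene not detected on any array of a group has only a bound there: its fold is given as "at least", from the brighter group's mean against the dim group's mean of, per array, the higher of the lowest detected value and the probe's own.

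All 12 arrays entered 1 limma model with a mean per group, moderated variances and a two-sided test per gene, with Benjamini-Hochberg adjustment over the 13577 genes and a threshold of 0.05. Errors given with log2 changes are standard errors from this model with n = 3 arrays per group, and errors given with levels are standard deviations. Gene lists fixed before the data were examined were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over all 135 list-by-comparison tests. The 27 lists covered ERK pathway output, ErbB receptors with their ligands and feedback, other receptor kinases and ligands, FOXO targets, DNA replication, mitosis, CDK inhibitors, the BCL2 family, type I interferon response, MHC class I presentation, NF-kB and inflammatory mediators, and STAT3 and acute phase. They also covered mesenchymal, epithelial and fibroblast markers, TGF-beta and YAP targets, hypoxia and glycolysis, cholesterol synthesis, fatty acid synthesis, ATF4 and amino acid response, ER chaperones, ribosome biogenesis, NRF2 targets, autophagy and lysosome, heat shock, lung epithelial differentiation, and drug tolerance and stem cell associated genes. Of 58 list calls, 41 held with an estimated correlation, and the p is given where a call was lost.

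The genes named in the text were chosen by a rule set before the data were examined. EGFR was always named. Per comparison, up to 10 genes with the largest rise and 10 with the largest fall were taken among those past the threshold whose replicates did not overlap (5 and 5 for the interaction, without the overlap condition). From each list described, up to 4 members with the largest change past the threshold, or else up to 2 with the smallest p, could be named, and for the fibroblast list also the 4 with the highest level. Chance alone leaves replicates of 3 against 3 without overlap in 10% of genes.

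The labels do not say whether the 3 arrays of a group came from separate cultures, so the p-values of single genes measure the spread between these arrays, which may be technical. The list test compares the members of a list with the other genes, so its p-values do not measure the spread between arrays alone. For mitosis with gefitinib in monoculture, the list adjusted p was 1.41e-33 at the preset correlation and 0.00172 with an estimated one. The replicate numbers were shared between groups, but of 18 same-numbered pairs only 1 had a correlation of deviations over 0.1 (range -0.0496 to 0.100), so the arrays were treated as unpaired. The number of arrays limits the precision. On simulated data for gefitinib in monoculture, with 200 of 13577 genes changed in each of 5 runs, 29.6% of changes of 0.5 log2 were recovered, 75.2% of changes of 1 and 98.2% of changes of 2, and 6.9% of the calls were false. For the interaction, 48.1% of changes of 1 log2 and 90% of changes of 2 were recovered. The share recovered depends on how many genes change. Far more were called in the data (4273 for gefitinib in monoculture and 2439 for the interaction), so these shares do not carry over directly. Alternatives to the background correction, normalization, probe filter, choice of probe, variance model, array weights, arrays in the fit, replicate block and each single array were run. No slide or scan batch was used here. The titles of all 6 co-culture arrays, and of no monoculture array, end in a shared suffix whose meaning is not given in the sources used here. A second planned measure of similarity across genes is not reported here. The software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.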

Results

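The study asked how HCC827 lung cancer cells respond to gefitinib in the short term when they share their medium with MRC-5 lung fibroblasts. RNA of the cancer cells was measured on 12 arrays, 3 each from DMSO monoculture, gefitinib monoculture, co-culture and co-culture with gefitinib. Between 43.4% and 46.5% of probes were detected on each array. Median scanner intensities were 99.1 to 103 on the 6 monoculture arrays and 106 to 110 on the 6 co-culture arrays. Across 13577 genes, arrays of the same group correlated with r between 0.986 and 0.991. Arrays from DMSO monoculture and gefitinib monoculture correlated with r between 0.963 and 0.966, and those from co-culture without and with gefitinib with r between 0.984 and 0.987.

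Gefitinib in monoculture lowered genes of cell division and of the ERK pathway and raised interferon and inflammatory genes. EGR1, an immediate early transcription factor, had a level of 9.74 ± 0.12 with DMSO and 5.77 ± 0.21 with gefitinib (SD, n = 3), a log2 change of -3.97 ± 0.12 (adjusted p = 2.45e-08). CCL2, a chemokine, rose by 3.91 ± 0.18 (adjusted p = 6.83e-08), and ACKR3, an atypical chemokine receptor, by 3.97 ± 0.23 (adjusted p = 2.49e-07). EGFR itself, the drug target, changed by -0.37 ± 0.11 (adjusted p = 0.0256), although 1 of its 3 other probes had the opposite sign. This call of EGFR ended without any 1 of the 6 monoculture arrays (adjusted p = 0.0504 to 0.0736). Of 13577 genes, 4273 changed, 2300 upward and 1973 downward, and 912 of them by at least 2-fold. With median scaling in place of quantile normalization the split was 1689 upward and 2347 downward.

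All 30 tested members of the mitosis list fell (30 adjusted over the list alone; median log2 change -2.09, list adjusted p = 1.41e-33). They included DLGAP5 at -2.50 ± 0.15, KIF2C at -2.42 ± 0.087 and CENPA, the centromeric histone, at -2.38 ± 0.10. Of the DNA replication list, 26 of 29 tested members (27 adjusted over the list alone) fell (median log2 change -1.25, list adjusted p = 2.07e-20). Among them were CDC45 at -2.27 ± 0.11, CDT1 at -2.24 ± 0.15 and TK1 at -2.15 ± 0.087. Ribosome biogenesis genes fell in 16 of 23 cases (18 down and 1 up adjusted over the list alone; median log2 change -0.51, list adjusted p = 4.17e-06). Examples were LYAR at -1.12 ± 0.098 and FBL at -0.64 ± 0.084. The largest falls also held NEK2 at -2.65 ± 0.086, DEPDC1 at -2.58 ± 0.16 and CDKN3 at -2.55 ± 0.10. CDKN3 belongs to the CDK inhibitor list, whose members CDKN1C (2.37 ± 0.16), CDKN2B (1.84 ± 0.11) and CDKN1B (0.98 ± 0.11) rose. Of its 7 tested members 4 rose and 2 fell, with equal counts adjusted over the list alone, and the list was not called (median log2 change 0.67, list adjusted p = 0.176).

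Genes driven by ERK signalling fell in 14 of 21 cases and rose in 1, with the same counts adjusted over the list alone (median log2 change -1.20, or -0.58 on the authors' values, list adjusted p = 3.08e-08). DUSP6, an ERK phosphatase, changed by -2.44 ± 0.10, ETV5 by -2.30 ± 0.16 and FOSL1 by -2.12 ± 0.12. Among ErbB ligands, HBEGF rose by 2.12 ± 0.11, whereas EREG (-1.22 ± 0.19) and BTC (-1.05 ± 0.12) fell. The chosen probe of NRG1, another ligand, also fell (-1.87 ± 0.092), but both other probes of NRG1 had the opposite sign. The ErbB list was not called (median log2 change -0.12, list adjusted p = 0.493). FOXO targets rose in 10 of 18 cases (11 adjusted over the list alone; median log2 change 0.39, list adjusted p = 3.32e-05). PIK3IP1, an inhibitor of PI3 kinase, rose by 2.36 ± 0.19. BMF, a pro-apoptotic member of the BCL2 family, rose by 2.66 ± 0.15, in a list that was not called (median log2 change 0.05, list adjusted p = 0.622).

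Type I interferon response genes rose in 28 of 36 cases (32 adjusted over the list alone; median log2 change 0.95, list adjusted p = 1.07e-13). Examples were OAS2 at 2.88 ± 0.19, MX2 at 2.33 ± 0.11 and IFI44L at 2.02 ± 0.10. NF-kB and inflammatory mediators rose in 15 of 24 cases, as many as adjusted over the list alone (median log2 change 0.56, list adjusted p = 1.48e-07). They included IL32, a cytokine, at 2.68 ± 0.15 and LCN2 at 2.21 ± 0.13. MHC class I genes rose in 9 of 15 cases and fell in 1 (10 and 1 adjusted over the list alone; median log2 change 0.52, list adjusted p = 1.83e-04). HLA-B rose by 1.59 ± 0.11. Autophagy and lysosome genes rose in 12 of 18 cases, unchanged adjusted over the list alone (median log2 change 0.51, list adjusted p = 3.04e-05). Among them were GABARAPL1 at 1.64 ± 0.17 and ULK1 at 1.37 ± 0.11.

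TGF-beta and YAP targets rose in 9 of 18 cases and fell in 1 (10 and 1 adjusted over the list alone; median log2 change 0.43, list adjusted p = 2.19e-04). Among the rises were ANKRD1 at 1.92 ± 0.11 and PMEPA1 at 1.87 ± 0.092. In these cultures without fibroblasts, 6 of 15 fibroblast markers rose and 1 fell (7 and 1 adjusted over the list alone). They included LUM at 1.40 ± 0.24, COL5A1 at 1.29 ± 0.14 and VIM at 1.17 ± 0.11. The list was not called (median log2 change 0.26, list adjusted p = 0.0664), but was called higher on the authors' normalized values (median 0.13) and with median scaling (median 0.25). Hypoxia and glycolysis genes fell in 17 of 21 cases (18 down and 1 up adjusted over the list alone; median log2 change -0.96, list adjusted p = 6.79e-12). VEGFA, an angiogenic factor, changed by -1.70 ± 0.13. Cholesterol synthesis genes fell in 13 of 18 cases and rose in 1, equally so adjusted over the list alone (median log2 change -0.63, or -0.37 on the authors' values, list adjusted p = 4.24e-05). INSIG1 changed by -1.49 ± 0.16, and TM7SF2 was the member that rose (1.56 ± 0.12). Fatty acid synthesis genes fell in 5 of 11 cases, also adjusted over the list alone (median log2 change -0.33, list adjusted p = 0.00168, adjusted p = 0.155 with an estimated correlation). ER chaperones fell in 5 of 15 cases (6 down and 1 up adjusted over the list alone; median log2 change -0.20, or -0.33 with median scaling, list adjusted p = 0.0155, adjusted p = 0.0578 with an estimated correlation).

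The other lists were not called in monoculture. Their median log2 changes were 0.05 for other receptor kinases and ligands (adjusted p = 0.622) and 0.17 for mesenchymal markers (adjusted p = 0.503). For STAT3 and acute phase the median was 0.03 (adjusted p = 0.668) and for epithelial markers 0.09 (adjusted p = 0.448), and both medians turned with median scaling, to -0.02 and -0.08. The medians were -0.15 for ATF4 and amino acid response (adjusted p = 0.0594), -0.20 for NRF2 targets (adjusted p = 0.627) and -0.20 for heat shock (adjusted p = 0.175). With median scaling the ATF4 and heat shock lists were called lower (medians -0.33 and -0.37). For lung epithelial differentiation it was 0.11 (adjusted p = 0.769). Drug tolerance and stem cell associated genes had a negative median of -0.16, a positive mean of 0.03 and an upward test (adjusted p = 0.919). Single members passed: AXL, a receptor kinase, fell by 1.59 ± 0.13, and GAS6, its ligand, rose by 1.42 ± 0.11, with 1 of its 3 other probes of opposite sign. The keratins KRT18 and KRT8 fell (-1.60 ± 0.12 and -1.42 ± 0.12), and KDM5B, a histone demethylase, rose by 1.15 ± 0.13. Without background correction some of the changes above were smaller, at 1.34 for OAS2, 2.19 for ACKR3, -1.11 for DUSP6 and -0.83 for AXL.

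**Figure D1:**
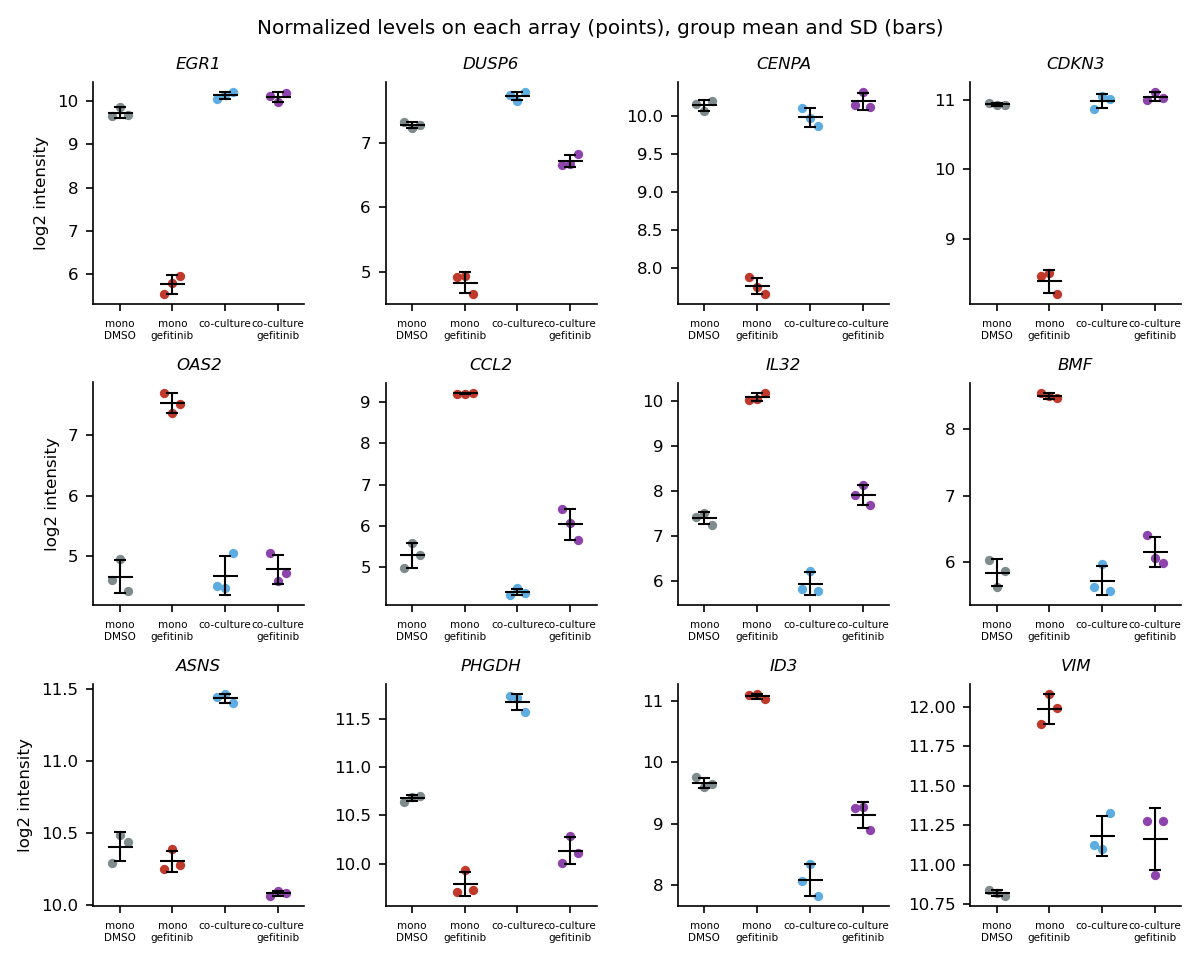
Normalized log2 intensity of 12 named genes on each of the 12 arrays (points, 3 per group), with the group mean and SD as bars; each panel has its own axis, which does not start at 0. EGR1 lies near 10 in both co-culture groups and at 5.77 in gefitinib monoculture, and ASNS is highest in co-culture without gefitinib.

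Gefitinib in co-culture raised inflammatory genes and lowered amino acid response and lipid synthesis genes. UBD, a ubiquitin-like protein induced by cytokines, rose by 2.13 ± 0.13 (adjusted p = 3.03e-05), IL32 by 1.96 ± 0.15 (adjusted p = 8.20e-05) and TRAF1 by 1.80 ± 0.12 (adjusted p = 3.70e-05). PHGDH, the first enzyme of serine synthesis, fell to a level of 10.13 ± 0.14 from 11.67 ± 0.087 (SD, n = 3), a change of -1.54 ± 0.10 (adjusted p = 3.03e-05). ASNS, asparagine synthetase, changed by -1.35 ± 0.084 (adjusted p = 3.03e-05). EGFR did not pass (-0.19 ± 0.11, adjusted p = 0.559). The level of EGR1 was 10.09 ± 0.11 against 10.13 ± 0.085 without the drug. Of 13577 genes, 204 changed, 84 upward and 120 downward, and 39 by at least 2-fold.

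Of the ATF4 and amino acid list, 10 of 26 tested members (17 adjusted over the list alone) fell (median log2 change -0.48, list adjusted p = 5.55e-21). They included TRIB3, a pseudokinase, at -1.05 ± 0.10 and PSAT1 at -0.93 ± 0.10. Cholesterol synthesis genes fell in 4 of 18 cases (12 adjusted over the list alone; median log2 change -0.28, list adjusted p = 2.46e-12). Among them were INSIG1 at -1.01 ± 0.16 and HMGCS1 at -0.97 ± 0.10. Fatty acid synthesis genes fell in 4 of 11 cases (8 adjusted over the list alone; median log2 change -0.42, list adjusted p = 6.75e-10). SCD, a desaturase, changed by -0.70 ± 0.085. ERK output genes fell in 3 of 21 cases (5 adjusted over the list alone; median log2 change -0.22, or -0.13 on the authors' values, list adjusted p = 3.32e-06). They were ETV5 at -1.07 ± 0.16, DUSP6 at -1.01 ± 0.10 and FOS at -0.66 ± 0.13. The call of ETV5 ended with the mean of its probes (-0.73). That of FOS ended without co-culture replicate 1 (-0.62) or 3 (-0.60) or gefitinib co-culture replicate 1 (-0.52), and with the replicate block (-0.66). SLC2A3, a glucose transporter, fell by 1.86 ± 0.15 within the hypoxia and glycolysis list. Of this list 4 of 21 fell (6 adjusted over the list alone; median log2 change -0.06, or -0.11 with median scaling, list adjusted p = 0.00256). NRF2 targets were lower as a list with 1 member past the test, AKR1B10 at -1.18 ± 0.19 (4 adjusted over the list alone; median log2 change -0.17, list adjusted p = 0.00326). The call of AKR1B10 ended without co-culture replicate 1 (-1.11) or gefitinib co-culture replicate 3 (-1.08).

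NF-kB and inflammatory mediators rose in 5 of 24 cases (10 up and 1 down adjusted over the list alone; median log2 change 0.21, or 0.13 on the authors' values, list adjusted p = 5.24e-07). CCL2 was not detected on any co-culture array without gefitinib and was at least 3.02-fold higher with it (adjusted p = 8.33e-04). Type I interferon genes rose in 3 of 36 cases (7 adjusted over the list alone; median log2 change 0.10, or 0.05 with median scaling, list adjusted p = 2.75e-04, adjusted p = 0.0557 with an estimated correlation). MHC class I genes rose in 1 of 15, HLA-B at 0.91 ± 0.11 (5 up and 1 down adjusted over the list alone; median log2 change 0.21, or 0.12 on the authors' values, list adjusted p = 8.85e-04, adjusted p = 0.0631 with an estimated correlation). TGF-beta and YAP targets rose in 4 of 18 cases, ID3 at 1.06 ± 0.14 among them, as many as adjusted over the list alone (median log2 change 0.07, or 0.04 with median scaling, list adjusted p = 0.0144, adjusted p = 0.0938 with an estimated correlation). The TGF-beta and YAP call ended without gefitinib co-culture replicate 1 (median 0.08). FOXO targets were called higher at the preset correlation with 2 of 18 members up (4 adjusted over the list alone; median log2 change 0.16, or 0.10 on the authors' values, list adjusted p = 0.00348, adjusted p = 0.113 with an estimated correlation), and this call ended without gefitinib co-culture replicate 3 (median 0.05). CDK inhibitors were called higher with 1 of 7 members up (3 adjusted over the list alone; median log2 change 0.07, or 0.03 with median scaling, list adjusted p = 0.0293, adjusted p = 0.0878 with an estimated correlation), and this call ended without co-culture replicate 1 (median 0.00968) or gefitinib co-culture replicate 2 (median 0.06). ER chaperones were called lower as a list, with 0 of 15 past limma's test, 1 down adjusted over the list alone and 3 at an unadjusted p under 0.05 (median log2 change -0.08, or -0.12 with median scaling, list adjusted p = 0.0439, adjusted p = 0.0938 with an estimated correlation). That call ended without co-culture replicate 1 or 2 (medians -0.08 and -0.07) or gefitinib co-culture replicate 1 or 3 (medians -0.11 and -0.08), and with the replicate block (median -0.08).

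Cell division genes were not called in this comparison. Of the mitosis list, 0 of 30 genes passed limma's test in either direction, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05 (median log2 change -0.00394, list adjusted p = 0.693). CENPA was at 0.21 ± 0.10, and the list's mean of 0.02 and its test were positive against a negative median, which turned to 0.00126 with cyclic loess. The DNA replication list had 0 of 29 members past limma's test, 0 adjusted over the list alone and 5 at an unadjusted p under 0.05 (median log2 change 0.08, list adjusted p = 0.0821), and was called higher on the authors' values (median 0.06). Fibroblast markers had 0 of 15 past limma's test (1 up and 0 down adjusted over the list alone, 2 at an unadjusted p under 0.05). The list was not called (median log2 change -0.02, list adjusted p = 0.944), and VIM was at -0.02 ± 0.11. The count of 204 was 61 when only the 6 co-culture arrays entered the model and 349 without background correction. It was 124 without co-culture replicate 1 and 130 without gefitinib co-culture replicate 3, and with median scaling 50 genes rose and 113 fell.

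Co-culture without gefitinib, against DMSO monoculture, raised amino acid response genes and lowered TGF-beta and YAP targets, ID genes among them. PCK2, a mitochondrial enzyme of gluconeogenesis, rose by 1.28 ± 0.11 (adjusted p = 3.88e-04), although 1 of its 2 other probes had the opposite sign. DEFB103B, a defensin, rose by 2.12 ± 0.24 (adjusted p = 0.00125) and was detected on 1 of 3 monoculture arrays and all 3 co-culture arrays. PTMA, RAD21 and HIF1A also rose (1.23 ± 0.18, 1.14 ± 0.13 and 1.11 ± 0.12). Another probe of RAD21 had the opposite sign, and its call ended with the mean of both (0.42). EDN1, endothelin, fell by 1.61 ± 0.10 (adjusted p = 6.85e-05), UBD by 1.80 ± 0.13 (adjusted p = 1.32e-04) and ID3 by 1.59 ± 0.14 (adjusted p = 3.88e-04). EGFR did not pass (0.13 ± 0.11, adjusted p = 0.604). Of 13577 genes, 480 changed, 223 upward and 257 downward, and 50 by at least 2-fold.

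The ATF4 and amino acid list rose in 14 of 26 cases (17 up and 1 down adjusted over the list alone; median log2 change 0.42, list adjusted p = 1.06e-17). They included ASNS at 1.03 ± 0.084, PSAT1 at 1.02 ± 0.10, PHGDH at 1.00 ± 0.10 and DDIT3 at 0.82 ± 0.13. This rise and the fall of the list with gefitinib in co-culture (median -0.48) share the 3 co-culture arrays without drug, so they are not independent results. ERK output genes rose in 4 of 21 cases (8 adjusted over the list alone; median log2 change 0.23, or 0.13 on the authors' values, list adjusted p = 2.02e-06). Among them were ETV5 at 1.06 ± 0.16, a call that ended with the mean of its probes (0.72), and FOS at 0.99 ± 0.13. TGF-beta and YAP targets fell in 7 of 18 cases (9 adjusted over the list alone; median log2 change -0.31, list adjusted p = 3.16e-06). They included ID2 at -1.22 ± 0.16, TGFB2 at -0.98 ± 0.12 and PMEPA1 at -0.87 ± 0.092. Type I interferon genes fell in 3 of 36 cases (6 adjusted over the list alone; median log2 change -0.20, or -0.12 on the authors' values, list adjusted p = 3.23e-04, adjusted p = 0.0572 with an estimated correlation). MHC class I genes fell in 2 of 15 (7 down and 1 up adjusted over the list alone; median log2 change -0.16, list adjusted p = 0.00507, adjusted p = 0.101 with an estimated correlation). Epithelial markers were called lower as a list, with 0 of 22 past limma's test, 3 down adjusted over the list alone and 7 at an unadjusted p under 0.05 (median log2 change -0.19, list adjusted p = 0.0173, adjusted p = 0.0717 with an estimated correlation). That call ended without DMSO monoculture replicate 3 (median -0.14) or co-culture replicate 2 (median -0.20). Fatty acid synthesis was called higher with 1 of 11 members up (2 adjusted over the list alone; median log2 change 0.06, or 0.10 with median scaling, list adjusted p = 0.0452, adjusted p = 0.335 with an estimated correlation). That call ended without DMSO monoculture replicate 2 or 3 (medians 0.06 and 0.07), co-culture replicate 1 or 3 (medians 0.04 and 0.08) or the probe filter, and with median scaling or the replicate block.

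Among the NF-kB and inflammatory mediators, IL32 fell by 1.46 ± 0.15 while CXCL8, a chemokine, rose by 0.45 ± 0.089. The call of CXCL8 ended with the mean of its probes, and without DMSO monoculture replicate 1, 2 or 3 (0.43, 0.42 and 0.48) or co-culture replicate 2 or 3 (0.40 and 0.46). The list was not called (median log2 change -0.01, list adjusted p = 0.794). Its median and mean were negative against an upward test, and the median turned to 0.01 with median scaling. Mitosis genes were not called (median log2 change -0.03, list adjusted p = 0.944), with 0 of 30 past limma's test, 0 adjusted over the list alone and 3 at an unadjusted p under 0.05. Fibroblast markers had 0 of 15 past limma's test in either direction, 1 up and 2 down adjusted over the list alone and 5 at an unadjusted p under 0.05 (median log2 change -0.15, list adjusted p = 0.622). Those whose probes had the highest mean intensity, which does not rank abundance across genes, were VIM, COL5A1, S100A4 and COL6A1. They changed by 0.36 ± 0.11, -0.33 ± 0.14, 0.37 ± 0.15 and -0.18 ± 0.096, and none of these passed, except that VIM passed without background correction (0.35) and on the authors' normalized values (0.34). The other probe of S100A4 had the opposite sign.

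The monoculture and co-culture arrays stood apart in other ways. All 6 co-culture arrays had another probe order in the scanner table. The titles of these 6 arrays, and of no monoculture array, end in a shared suffix whose meaning is not given. In addition, 4 of 9 neighbouring probes without a gene name here were higher on co-culture arrays by 1.10 to 1.55 on the log2 scale without gefitinib and by 1.16 to 1.61 with it. Each culture lay within 1 such set of arrays, so the design does not separate the set from the culture in comparisons of co-culture with monoculture. A set difference that acts alike in both drug states cancels from the interaction, so it would not account for that of the mitosis list (median 2.08). That value does not say whether such a difference is present in this comparison, where the mitosis list was not called (median -0.03). The count of 480 was 155 with only the 6 arrays compared and 912 without background correction. It was 222, 182 and 154 without DMSO monoculture replicates 1, 2 and 3, and 229, 203 and 300 without co-culture replicates 1, 2 and 3. With median scaling 149 genes rose and 103 fell.

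Cell division and ERK output genes were higher, and interferon and inflammatory genes lower, in co-culture with gefitinib than in gefitinib monoculture. EGR1 rose by 4.33 ± 0.12 (adjusted p = 4.72e-09) and NEK2, a mitotic kinase, by 3.20 ± 0.086 (adjusted p = 4.72e-09). FOXM1, a transcription factor of the cell cycle, had a level of 8.85 ± 0.21 in co-culture and 6.25 ± 0.27 in monoculture (SD, n = 3), a change of 2.60 ± 0.16 (adjusted p = 4.07e-07). ACTA1, skeletal muscle actin, was not detected on any array of co-culture with gefitinib and was at least 11.1-fold lower there (adjusted p = 7.51e-07), and CCL2 fell by 3.16 ± 0.18 (adjusted p = 2.89e-07). EGFR did not pass (0.30 ± 0.11, adjusted p = 0.0549), but passed without background correction (0.29), on the authors' normalized values (0.27), with the mean of its probes, with the replicate block and without gefitinib co-culture replicate 2 (0.39). Of 13577 genes, 4799 changed, 1972 upward and 2827 downward, and 1033 by at least 2-fold. With median scaling the split was 2220 upward and 2175 downward. The 3 gefitinib monoculture arrays also enter the comparison of gefitinib in monoculture and the interaction, so these are not independent results. Of the 1972 genes higher here, 1460 were lowered by gefitinib in monoculture. Of the 2827 lower here, 1970 were raised by it.

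All 30 mitosis genes rose, also adjusted over the list alone (median log2 change 2.07, list adjusted p = 5.30e-33). Examples were BUB1 at 2.54 ± 0.090 and PLK1 at 2.44 ± 0.11. DNA replication genes rose in 25 of 29 cases (26 adjusted over the list alone; median log2 change 1.16, list adjusted p = 4.14e-20). RRM2, a subunit of ribonucleotide reductase, rose by 2.14 ± 0.14. ERK output genes rose in 14 of 21 cases and fell in 2 (15 and 2 adjusted over the list alone; median log2 change 1.10, or 0.72 on the authors' values, list adjusted p = 6.36e-09). PHLDA1 rose by 2.09 ± 0.11. Hypoxia and glycolysis genes rose in 16 of 21 cases and fell in 1, as adjusted over the list alone (median log2 change 0.73, list adjusted p = 5.72e-08). HK2, a hexokinase, rose by 1.73 ± 0.13. Ribosome biogenesis genes rose in 16 of 23 cases, also adjusted over the list alone (median log2 change 0.46, list adjusted p = 1.22e-06).

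Interferon genes fell in 31 of 36 cases and rose in 1 (32 and 1 adjusted over the list alone; median log2 change -0.94, list adjusted p = 4.87e-13). OAS2 changed by -2.75 ± 0.19. MHC class I genes fell in 12 of 15 cases, also adjusted over the list alone (median log2 change -0.53, or -0.33 with median scaling, list adjusted p = 1.11e-04). NF-kB and inflammatory mediators fell in 13 of 24 cases and rose in 1 (15 and 1 adjusted over the list alone; median log2 change -0.46, list adjusted p = 4.08e-04). LCN2, an iron-binding protein of inflammation, changed by -1.43 ± 0.13. Autophagy and lysosome genes fell in 13 of 18 cases and rose in 1, as adjusted over the list alone (median log2 change -0.67, list adjusted p = 5.04e-05). FOXO targets fell in 10 of 18 cases, likewise adjusted over the list alone (median log2 change -0.34, list adjusted p = 0.00326, adjusted p = 0.112 with an estimated correlation). Epithelial markers fell in 12 of 22 and rose in 2, likewise adjusted over the list alone (median log2 change -0.40, or -0.24 with median scaling, list adjusted p = 0.0239, adjusted p = 0.0826 with an estimated correlation). The epithelial list call ended with median scaling.

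TGF-beta and YAP targets fell in 12 of 18 cases (13 adjusted over the list alone; median log2 change -0.60, list adjusted p = 3.32e-06). PMEPA1 changed by -2.25 ± 0.092. Of the fibroblast markers, 6 of 15 fell, also adjusted over the list alone, with COL5A1 at -1.86 ± 0.14 and VIM at -0.83 ± 0.11. The list was not called (median log2 change -0.49, list adjusted p = 0.0594), but was called lower without gefitinib monoculture replicate 2 (median -0.63) or gefitinib co-culture replicate 2 (median -0.63) and with median scaling (median -0.48). The ATF4 and amino acid list was not called (median log2 change 0.03, list adjusted p = 0.216), with 7 members up and 2 down of 26, as adjusted over the list alone. With median scaling it was called higher (median 0.16). The 4 unnamed probes above were higher on these co-culture arrays too, and the design does not separate the array set from the culture here either. For the mitosis and DNA replication lists, the values argue against a set difference that acts alike with and without the drug. Their medians were -0.03 and -0.14 in co-culture without gefitinib, against 2.07 and 1.16 here. A set difference that depends on the drug is not excluded.

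**Figure D2:**
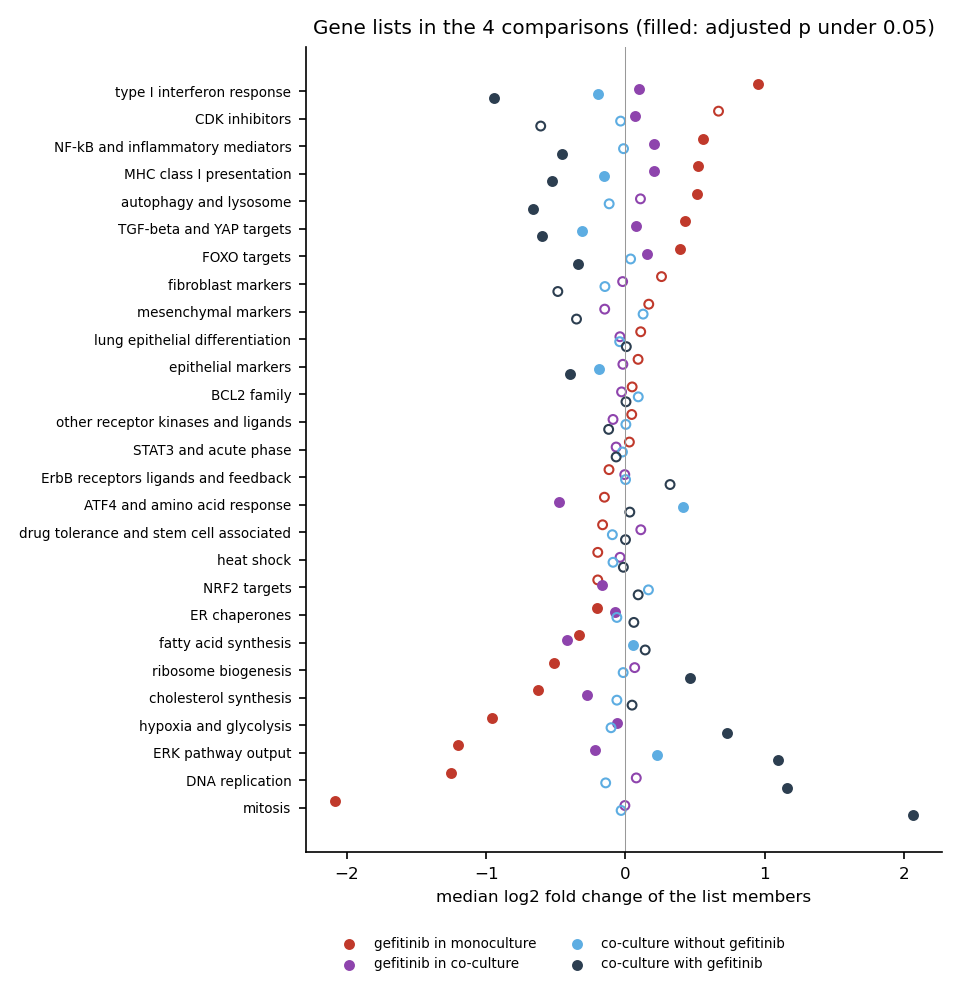
Median log2 fold change of the tested members of each of the 27 gene lists (rows) in 4 comparisons (colours); filled points passed the list test at an adjusted p under 0.05 and open points did not. The mitosis list lies at -2.09 for gefitinib in monoculture, at -0.00394 for gefitinib in co-culture and at 2.07 for co-culture with gefitinib.

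The interaction tested whether the gefitinib effect differed between cultures, and a positive value means that the drug lowered a gene less, or raised it more, in co-culture. EGR1 had an interaction of 3.93 ± 0.17 (adjusted p = 1.22e-06), FST, a binding protein of activin, of 2.72 ± 0.19 (adjusted p = 5.07e-06) and CENPA of 2.59 ± 0.14 (adjusted p = 2.14e-06). ACKR3 had -3.49 ± 0.32 (adjusted p = 3.38e-05) and OAS2 -2.76 ± 0.27 (adjusted p = 5.14e-05). TCIM was detected on all 3 arrays of gefitinib monoculture and on no other array, so that its interaction has no exact size. EGFR did not pass (0.17 ± 0.16, adjusted p = 0.511). The effect differed for 2439 of 13577 genes, 1094 with a positive and 1345 with a negative interaction, and 797 by at least 2-fold. With median scaling 1063 were positive and 972 negative.

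All 30 mitosis genes had a positive interaction, also adjusted over the list alone (median log2 change 2.08, list adjusted p = 3.83e-41). So had 24 of 29 DNA replication genes (25 positive and 1 negative adjusted over the list alone; median log2 change 1.39, list adjusted p = 2.89e-24). Positive interactions were also found for 12 of 21 tested members (12 adjusted over the list alone) of ERK pathway output (median log2 change 0.93, or 0.37 on the authors' values, list adjusted p = 1.13e-07). They included FOSL1 at 1.88 ± 0.17 and DUSP6 at 1.43 ± 0.14. The same held for 14 of 21 tested members (16 adjusted over the list alone) of hypoxia and glycolysis (median log2 change 0.82, list adjusted p = 5.47e-10). It held for 13 of 23 tested members (17 adjusted over the list alone) of ribosome biogenesis (median log2 change 0.57, list adjusted p = 6.85e-07). Negative interactions were found for 22 of 36 tested members (23 adjusted over the list alone) of the interferon list (median log2 change -0.80, list adjusted p = 1.60e-11), with MX1 at -1.61 ± 0.13. They were also found for 8 of 18 tested members (10 adjusted over the list alone) of autophagy and lysosome (median log2 change -0.53, list adjusted p = 8.66e-05). NF-kB and inflammatory mediators had 10 negative and 1 positive of 24 (11 and 1 adjusted over the list alone; median log2 change -0.44, or -0.28 on the authors' values, list adjusted p = 3.61e-05). The ATF4 and amino acid list had 8 negative and 1 positive of 26 (11 and 1 adjusted over the list alone; median log2 change -0.37, or -0.24 with median scaling, list adjusted p = 0.00139), with ASNS at -1.25 ± 0.12. FOXO targets were called negative with 7 of 18 members negative (9 adjusted over the list alone; median log2 change -0.38, list adjusted p = 7.57e-04, adjusted p = 0.0820 with an estimated correlation). So were MHC class I presentation with 6 of 15 members negative (7 adjusted over the list alone; median log2 change -0.40, list adjusted p = 0.00509, adjusted p = 0.101 with an estimated correlation) and TGF-beta and YAP targets with 6 negative and 1 positive of 18 (7 and 1 adjusted over the list alone; median log2 change -0.39, list adjusted p = 0.00366, adjusted p = 0.0578 with an estimated correlation). Fibroblast markers were not called (median log2 change -0.46, list adjusted p = 0.114), except that the list was called negative without gefitinib co-culture replicate 2 (median -0.32).

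Across genes, which are not independent replicates, the gefitinib changes in monoculture and co-culture correlated with Pearson r = 0.248. These comparisons share no arrays. Over the 4273 genes called in monoculture, the mean signed change in co-culture was 0.105 times that in monoculture, and 61.5% had the same sign. Over the 204 genes called in co-culture, the mean signed change in monoculture was 1.33 times that in co-culture. Of the 84 genes that gefitinib raised in co-culture, 75 were also raised in monoculture, against 14.2 for independent lists. Of the 120 that it lowered, 74 were also lowered in monoculture, against 17.4. IL32 and DUSP6 are among them. The co-culture changes without and with gefitinib correlated with r = 0.327. Both set co-culture arrays against monoculture arrays, so a difference between the array sets would enter both and could raise this r.

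**Figure D3:**
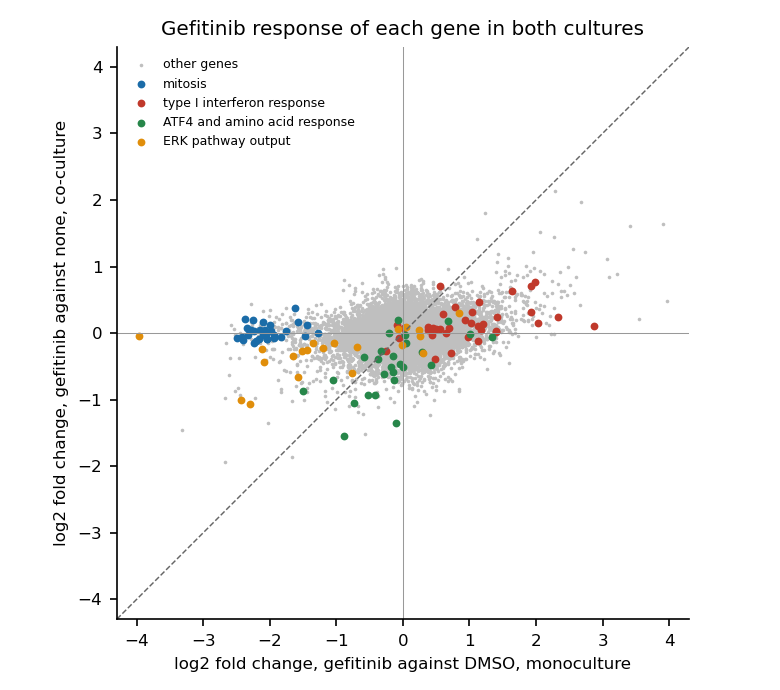
Log2 fold change with gefitinib in monoculture (horizontal) and in co-culture (vertical) for each of the 13577 genes; members of 4 lists are coloured and the dashed line marks equal changes. Mitosis genes lie far to the left with co-culture changes near 0, and ATF4 and amino acid genes lie mostly below 0 in co-culture.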

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

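The tests of dynamic range, of exposure, of the array sets and of the medium, and the reassigned drug labels, were chosen only after the results were seen; those of fibroblast RNA and of other splits were written before. The gefitinib effect differed between the cultures for 2439 genes by limma's interaction test. When the 12 arrays were assigned to 4 groups of 3 at random, 1 of 100 assignments, the real one, gave as many genes, and the highest other gave 1. When the drug labels were reassigned among the co-culture arrays alone, the 19 other assignments gave between 2170 and 3162 genes. Random assignments mix the monoculture drug effect into the spread within groups, so they speak only to whether any of the 4 groups differed and not to the interaction by itself. With the monoculture labels kept, 12 of 20 assignments gave as many genes, the real one included, so a count of this size does not need the real co-culture drug labels. For the comparisons of 3 against 3 arrays the 10 possible splits are too few for a share under 0.05. There the real value and the highest other were 4273 and 0 genes for gefitinib in monoculture, 204 and 2 for gefitinib in co-culture, 480 and 1 for co-culture without gefitinib, and 4799 and 0 for co-culture with gefitinib. In each, 1 split, the real one, gave as many.

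The single genes with the largest interactions were EGR1 (3.93), FST (2.72), DEPDC1 (2.70), CDKN3 (2.61) and CENPA (2.59) upward, and ACKR3 (-3.49), ACTA1 (-3.35), OAS2 (-2.76), SBK1 (-2.33) and TCIM (-2.28) downward on the log2 scale. ACTA1 was not detected on any co-culture array and TCIM only in gefitinib monoculture, so their fitted values depend on the background and are neither exact sizes nor bounds. The lists with an interaction had median values of 2.08 (mitosis), 1.39 (DNA replication), 0.93 (ERK pathway output), 0.82 (hypoxia and glycolysis) and 0.57 (ribosome biogenesis). On the negative side they were -0.80 (type I interferon response), -0.53 (autophagy and lysosome), -0.44 (NF-kB and inflammatory mediators), -0.40 (MHC class I presentation), -0.39 (TGF-beta and YAP targets), -0.38 (FOXO targets) and -0.37 (ATF4 and amino acid response). The calls of MHC class I presentation (adjusted p = 0.101), TGF-beta and YAP targets (adjusted p = 0.0578) and FOXO targets (adjusted p = 0.0820) were lost with an estimated correlation. On the authors' values the ERK median was 0.37 and the NF-kB median -0.28, and with median scaling the ATF4 median was -0.24.

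Gefitinib changed 4273 genes in monoculture and 204 in co-culture. A lower dynamic range on the co-culture arrays is argued against by a slope of 0.990 across genes of the co-culture on the DMSO monoculture levels before normalization between arrays, where a value of 0.5 or lower would be needed; single DMSO arrays gave 0.982 to 1.01 against the others. Dilution by fibroblast RNA, which the insert should keep out, is argued against by a median log2 change of -0.147 in the fibroblast list (7 of 15 detected on all DMSO monoculture arrays) in co-culture without gefitinib. SPARC, COL1A2 and FN1, abundant in fibroblasts, were detected on 0, 1 and 1 of the 3 co-culture arrays. They were chosen after their values were seen and add no support. Among the markers with the brightest probes, VIM and S100A4 were higher there and COL5A1 and COL6A1 lower. None of these passed, except VIM without background correction and on the authors' values. A lower effective exposure to gefitinib in the co-culture arm would shrink the drug responses, as in the ERK list (median -0.221 there). The median of the ATF4 list (-0.48 in co-culture against -0.15 in monoculture) was no nearer to 0 in co-culture. However, this list started higher in co-culture without the drug (median 0.42 against DMSO monoculture), on the same 3 arrays. With the drug its median against gefitinib monoculture was 0.03, or 0.16 with median scaling. Its larger fall came from a raised level and so does not decide on exposure. Fatty acid synthesis does not decide this either. Its median was -0.42 against -0.33, but its mean was nearer to 0 in co-culture (-0.39 against -0.50), and its interaction was not called (list adjusted p = 0.619). With median scaling the ATF4 medians were -0.52 and -0.33 and their difference did not pass with an estimated correlation. Lower exposure thus stays open and cannot be told apart from an effect of the fibroblasts, the biological explanation that the design names, which was not tested separately. The medium of the monoculture arms is not given, so a difference of medium between the cultures stays open too.

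Probes without a gene name here, which are in no gene count above, also separated the cultures: of 7658 detected, 366 differed between co-culture and DMSO monoculture, 308 of them higher. That was 4.78% of these probes against 3.21% of genes adjusted together with them. In each other comparison their share was below that of genes, as for gefitinib in monoculture (11.9% against 28.2%). The probes ILMN_1343061 and ILMN_1343062 were higher by 1.55 and 1.43 on the log2 scale. Separate processing of the 2 sets of arrays may account for part of the genes and probes that differed whatever the drug. Of 9 unnamed probes near the start of the probe list, 4 were higher in co-culture in both drug states and 5 did not pass in either. These probes were chosen after their values had been seen and may be controls of the array. Since each culture holds arrays of 1 set only, this cannot be told apart from the culture itself.

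The ATF4 and amino acid list was higher in co-culture without gefitinib than in DMSO monoculture (median log2 change 0.42, list adjusted p = 1.06e-17). The medium of the co-culture arms, acting alike with and without the drug, would leave an interaction near 0. The median interaction was -0.370, but -0.24 with median scaling, where the list test did not pass with an estimated correlation. An additive difference between the array sets would give a median above 0.2 in co-culture with gefitinib, where it was 0.0313, but 0.16 and called with median scaling. Both thus stay open and cannot be told apart from an effect of the fibroblasts, which was not tested separately.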

How the results depend on the processing

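The settings with arrays normalized alone or in the deposited order, and the list tests with median scaling and cyclic loess, were chosen after seeing the data; the others were set before the data were examined. Counts for gefitinib in monoculture, co-culture with gefitinib and the interaction stayed within 1.5 times of the value reported under every alternative run. Gefitinib in co-culture (204 genes) gave 349 without background correction, 346 on the authors' normalized values, 387 with an intensity trend and robust variances, 61 with only its own arrays in the model and 59 with them also normalized alone. Co-culture without gefitinib (480) gave 912, 903, 1001 and 155 in the same order, and 252 with median scaling. Models of 6 arrays have fewer degrees of freedom; the cause of the other shifts was not tested. The 6 monoculture arrays alone, in the deposited order, gave 4290 genes against 4273, 3931 of them shared.

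Leaving out single arrays gave 3568 to 3707 genes for gefitinib in monoculture, 124 to 171 for gefitinib in co-culture, 154 to 300 for co-culture without gefitinib, 4109 to 4394 for co-culture with gefitinib and 1979 to 2261 for the interaction. For list calls the ranges were 14 to 15, 11 to 13, 5 to 7, 12 to 13 and 12 to 13. With the replicate block the counts were 4181, 153, 332, 4742 and 2322 genes, all within 1.5 times, and the block ended 2 list calls, ER chaperones with gefitinib in co-culture and fatty acid synthesis in co-culture without gefitinib. The shared numbers were not treated as pairs, since same-numbered arrays did not deviate together.

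With an estimated correlation, list calls went from 13 to 7 for gefitinib in co-culture and from 7 to 3 for co-culture without gefitinib. Fry, which does not compare a list with other genes, called 22 lists for gefitinib in monoculture, 14 for co-culture without gefitinib, 23 for co-culture with gefitinib and 22 for the interaction. Of 58 list calls, the median moved by more than 1.5 times in 10 with median scaling, in 0 with cyclic loess and in 11 on the authors' values, and 56, 58 and 58 were still called in the same direction. The cause of these moves was not tested.

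For the gefitinib effect in both cultures, r (0.248) was 0.313 without background correction, 0.313 on the authors' values and 0.222 without the probe filter, and 0.214 to 0.248 without single arrays. The ratio over genes called in monoculture was 0.0995, 0.0997 and 0.120 with no background correction, the authors' values and median scaling, and 0.0990 to 0.109 without single arrays, and that over genes called in co-culture 1.45, 1.45 and 1.21 in the same order, with 1.20 to 1.35. For the co-culture effect, r with no background correction and the authors' values was 0.386, 0.387 and, with no filter, 0.300 (0.300 to 0.328 without single arrays).

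For the 504 values of named genes, the mean of all probes ended 37 calls, the replicate block 27 and no background correction 5, and leaving out single arrays ended 311 calls in 3618 cases. No call turned its direction under the settings run. Without background correction 142 of 449 called values moved by more than 1.5 times, on the authors' values 144, with the mean of all probes 48 and with the replicate block 0. Of values that had not passed, with gefitinib in co-culture VIM became 0.0422 and WDR12 0.0854 with the mean of all probes, and without single arrays VIM lay between -0.0771 and 0.0929 and the fibroblast list between -0.0771 and 0.170. A block for slide or scan batch was not run, since the values used here carry none, and the interaction already uses all 4 groups. Signal near background limits dim genes.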

Other observations

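After the data had been seen, gefitinib-treated cells in co-culture were also compared with DMSO monoculture. They differed in 415 genes, 169 higher and 246 lower, 64 of them by at least 2-fold. A score per array, the mean over genes that gefitinib raised in monoculture minus that over genes it lowered, relative to DMSO monoculture, ranged from 1.54 to 1.56 on the 3 gefitinib monoculture arrays. It ranged from 0.093 to 0.125 on the gefitinib co-culture arrays and from -0.0616 to -0.0477 on the co-culture arrays without drug. The genes were chosen on the monoculture arrays, so the monoculture scores are not independent evidence. The co-culture scores are not fully independent of that choice either, since their reference, the DMSO monoculture arrays, was used in it. They also set arrays of one set against those of the other.

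Some genes that differed between co-culture without gefitinib and DMSO monoculture went the other way with gefitinib. Of 223 genes higher and 257 lower in co-culture without gefitinib, 42 and 55 went the other way with the drug in co-culture, against 1.97 and 1.59 for independent lists. UBD, EDN1, IL32, TRAF1 and NPPB were lower in co-culture (-1.80, -1.61, -1.46, -1.23 and -1.23) and rose with gefitinib there (2.13, 1.52, 1.96, 1.80 and 1.41). Both comparisons share the 3 co-culture arrays without drug, which alone gives a negative relation. The covariance across genes was -0.0296, against -0.0160 in 100 simulations of unchanged groups, and r was -0.445 against -0.500. These values do not say how much of the overlap comes from the shared arrays, which are too few to be split.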
